A study of Lactuca sativa with 18 samples.

How the data were processed

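RNA sequencing was carried out on leaf midribs of 3 romaine lettuce (Lactuca sativa) cultivars: Tall Guzmaine (TG), which browns strongly after cutting, Parris Island Cos (PC), which browns little, and Clemente (CL), a line of medium browning that was selected from a cross of PC and TG. Per the labels' protocols, the harvested heads were cooled, trucked to the laboratory under refrigeration and held cold for a further day, after which midribs were cut by hand into short pieces, kept in the cold and frozen on day 0, day 2 or day 3. Each of the 9 combinations of cultivar and day had 2 samples. Per the labels' protocols, total RNA was extracted with a column kit and sequenced as paired-end reads on an Illumina HiSeq3000. The labels do not say whether the 2 samples of a group came from separate heads, so p-values measure only the spread between these samples, which may be partly technical.

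The deposited values are counts per NCBI GeneID, with 64021 rows in each sample's table, per the file contents. The submitters' processing notes name FastQC, Trim Galore, STAR 2.4.0i, featureCounts, R 3.6.1 and DESeq2, with no role or order. The genome build, the annotation and the strand setting are not given in the sources used here. Between 68.4% and 74.6% of the values of 100 or more were even in the day 0 and day 3 columns, as when both mates of a read pair are counted, so the number of independent fragments lies below the count. The rows held 46150 distinct GeneIDs, of which 7574 stood on more than one row. Their counts were summed per GeneID, and they made up 0.43% to 0.63% of the counts in a day 0 or day 3 library. Totals ran from 35603537 to 59153901 counts in these 12 libraries.

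The authors' deposited day 2 columns were treated as a score derived from other columns and not as counts. In each of the 6 day 2 columns, between 98.9% and 99.8% of the rows with at least 200 day 0 and day 3 counts lay within 1 count of a single factor times the mean of the day 0 and day 3 columns of the same cultivar and replicate number, after a single constant had been added to that mean. The factors ran from 0.99 to 1.05 and the constants from -2 to 2. The other 435 rows of this size, over the 6 columns, lay within 1 count of the plain mean of day 0 and day 3. In rows with 1 to 199 counts, 45.5% to 100% of a column lay within 1 count of the scaled value, and the largest deviation was 4.0 counts. Where day 0 and day 3 were both 0, up to 391 rows of a column were not, with values of at most 2, and no single formula gave these. How these columns came about is not given in the sources used here. Because nearly all of their values could be computed from day 0 and day 3, all tests used the 12 day 0 and day 3 libraries. The comparisons planned for day 2 (TG against PC, each cultivar against its day 0, day 3 against day 2, and the difference in day 2 response) were not run. The comparisons of CL with its parents averaged day 0 and day 3 in place of 3 days.

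Genes were filtered with filterByExpr by group in edgeR 4.0.16 under R 4.3.3, which left 21757 genes. Library sizes were scaled by TMM factors, and a robust quasi-likelihood model with a mean for each of the 6 cultivar and day groups was fitted to all 12 libraries, which share an estimate of the spread. Each comparison was a contrast of that model, tested with the quasi-likelihood F-test and adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are given as CPM, the counts scaled by TMM-adjusted library size, as mean and SD of 2 libraries. Where both libraries of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio carries a 95% exact (Clopper-Pearson) interval. Floors and intervals take each count as independent and leave out the spread between replicates. If both mates of a pair were counted, fragments are fewer than counts. The intervals are then too narrow and the lower bounds too high. Replicates differed by more than sampling noise in all 6 tested groups. The chi-square over degrees of freedom on halved counts was 56.7 to 84.9 in the day 0 groups and 11.2 to 36.8 in the day 3 groups. The same model was tested on simulated negative binomial counts for the 21757 genes with 200 changed genes per comparison. For TG against PC at day 0 it recovered 12% of the 2-fold and 61% of the 4-fold changes. The corresponding shares were 6% and 55% for day 3 against day 0 in PC, 27% and 70% for CL against PC over days, and 0% and 17% for the difference in storage response. Far more genes passed in the data, 30.4% for TG against PC at day 0 and 12.2% for the difference in response. The adjusted threshold was therefore stricter in the simulation, and its shares do not give the recovery in the data.

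GeneIDs were matched to the NCBI name table of assembly Lsat_Salinas_v11, which gave names to 40695 of the 46150 GeneIDs. All but 7 of these names are locus numbers or tRNA names and none carries a product, so the 32 gene lists fixed beforehand, among them polyphenol oxidase, phenylalanine ammonia-lyase and the markers of other midrib cell types, matched 0 genes and could not be tested. A GeneID without a name is written GeneID_ and its number. The assembly was used only for names and for the order of neighbouring genes. The rule for naming genes, fixed before the data were examined, allowed in this case 2 genes higher and 2 lower per comparison. For TG against PC these were taken from genes past the threshold on both days in the same direction, and for storage from genes past it in all 3 cultivars in the same direction, in each case with both libraries of one group beyond both of the other, ranked by the smallest of the fold changes. For the other comparisons the genes with the highest and lowest log2 fold changes were taken. All had a mean log2 CPM of at least 1. Genes of a family that share reads, overlapping genes and antisense genes cannot be told apart without the counting settings, and their values are uncertain. A count of 0 shows only that no read was assigned to the gene. Whether reads of a cultivar failed to match the reference used for counting was not tested.

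Alternatives fixed before the data were examined were RLE factors, as DESeq2 uses them, in place of TMM, the DESeq2 1.42.0 Wald test, no filter and a stricter filter on low counts (at least 1 CPM in 2 libraries and 50 counts in all), the replicate number as a block, a fit with only the groups compared, a 2-fold minimum, and leaving out each library in turn. Alternatives added after seeing the data were all 18 columns taken as counts, no scaling factor, halved counts, rows kept apart, leaving out the 100 most abundant genes, and thinning every library to 35603537 counts. Also chosen after seeing the data were the comparisons of CL with each parent on single days, the differences in storage response that involve CL, the classes of CL between its parents and the genes counted as on or off. Without a scaling factor, the median log2 fold change moved by -0.22 for TG against PC at day 0, -0.34 for CL against PC and -0.20 for CL against TG over days, 0.33 for day 3 against day 0 in CL, and 0.16 for the difference in storage response of TG and PC. Directions are therefore relative to the TMM scaling, which assumes that most genes did not change. Tables and plots were made with Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9.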

Results

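Midrib pieces of 3 romaine cultivars that differ in enzymatic browning, the discoloration of cut tissue as phenolic compounds are oxidised, were sequenced on day 0 and after 3 days of cold storage. TG is the high-browning parent, PC the low-browning parent and CL a medium-browning line selected from their cross. The 12 libraries tested held 35603537 to 59153901 counts, and each of the 6 groups had 2 libraries. The deposited day 2 values lay within a few counts of scaled means of day 0 and day 3, apart from rows described with the methods, and were not used. Pearson correlations of log2 CPM across genes were 0.961 to 0.979 between the replicates of a group. The first principal component held 37.5% of the variance and separated day 0 from day 3. The second held 28.7% and separated the cultivars within each day, more widely at day 0 than at day 3, but not across days. The third held 11.1% and set TG apart from PC and CL on both days.

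**Figure D1:**
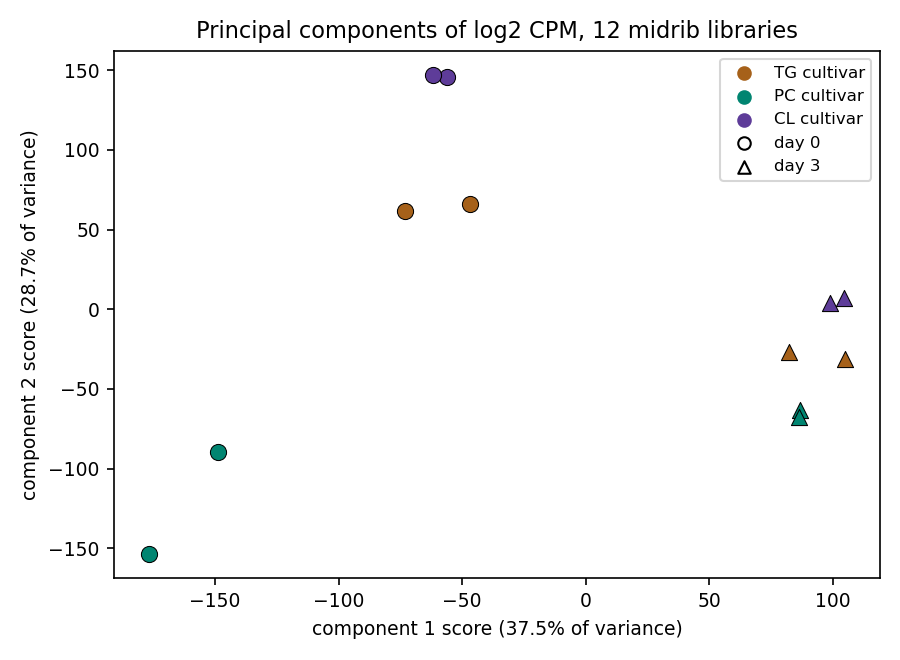
Scores of the 12 day 0 and day 3 libraries on the first and second principal components of log2 CPM, with colour for the cultivar and shape for the day. The 6 day 3 libraries lie between 82.1 and 104.9 on component 1, while day 0 libraries lie between -176.7 and -47 and are spread by cultivar on component 2 from -153.5 to 147.2.

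The comparison of TG with PC asks how the high-browning cultivar differs from the low-browning cultivar. At both days LOC111921163 was expressed in TG, at 65.81 ± 2.32 CPM on day 0 and 52.53 ± 10.5 CPM on day 3 (SD, n = 2), with 0 counts in the 4 PC libraries, so that it was at least 928-fold higher in TG on day 0 and at least 835-fold higher on day 3. GeneID_111886954 was likewise at 0 counts in PC and at 21.95 ± 6.42 CPM on day 0 and 24.29 ± 7.48 CPM on day 3 in TG, at least 310-fold and at least 386-fold higher. Why PC had 0 counts of LOC111921163 and GeneID_111886954 was not tested. In the other direction, GeneID_111888072 stood at 65.11 ± 10.8 CPM in PC on day 0 against 2 counts in TG, a ratio of 3158. Its 95% counting interval of 874 to 26084 takes each count as independent and is too narrow if both mates were counted. LOC111900676 stood at 54.2 ± 1.78 CPM in PC on day 0 against 4 counts in TG. The TG counts of both genes on day 0 lay in replicate 1 and below the floor on average, so the sizes rest on that library. Without it the fitted log2 fold change, which then depends on the prior count, moved from -11.45 to -14.52 for GeneID_111888072 and from -10.28 to -14.26 for LOC111900676, and without replicate 2 to -10.65 and -9.43. LOC111900676 was at least 648-fold higher in PC on day 3, where TG had 0 counts. The adjusted p-values of these 4 genes lay between 6.15e-06 and 6.2e-05 on day 0 and between 1.44e-05 and 0.00016 on day 3 (edgeR quasi-likelihood test, Benjamini-Hochberg).

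Over all genes, 6609 of 21757 differed between TG and PC on day 0, 3752 of them higher and 2857 lower in TG, and 4801 of these also changed at least 2-fold. On day 3 the number was 316, with 157 higher and 159 lower in TG, although 2431 genes had an unadjusted p under 0.05. The median absolute log2 fold change between TG and PC was 0.73 on day 0 and 0.32 on day 3 (0.71 and 0.31 with groups at 0 counts set to the floor). Of the day 3 genes, 133 were higher and 132 lower in TG on both days, where independent lists would share 27 and 21. The day 0 count fell to 3813 without PC day 0 replicate 2 and to 2873 in a fit of only those 2 groups, and without a scaling factor its split turned to 2902 higher and 3968 lower. The day 3 count was between 126 and 179 without any one of its 4 libraries, 889 in a fit of only those 2 groups, 833 with DESeq2 and 608 with all 18 columns taken as counts.

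**Figure D2:**
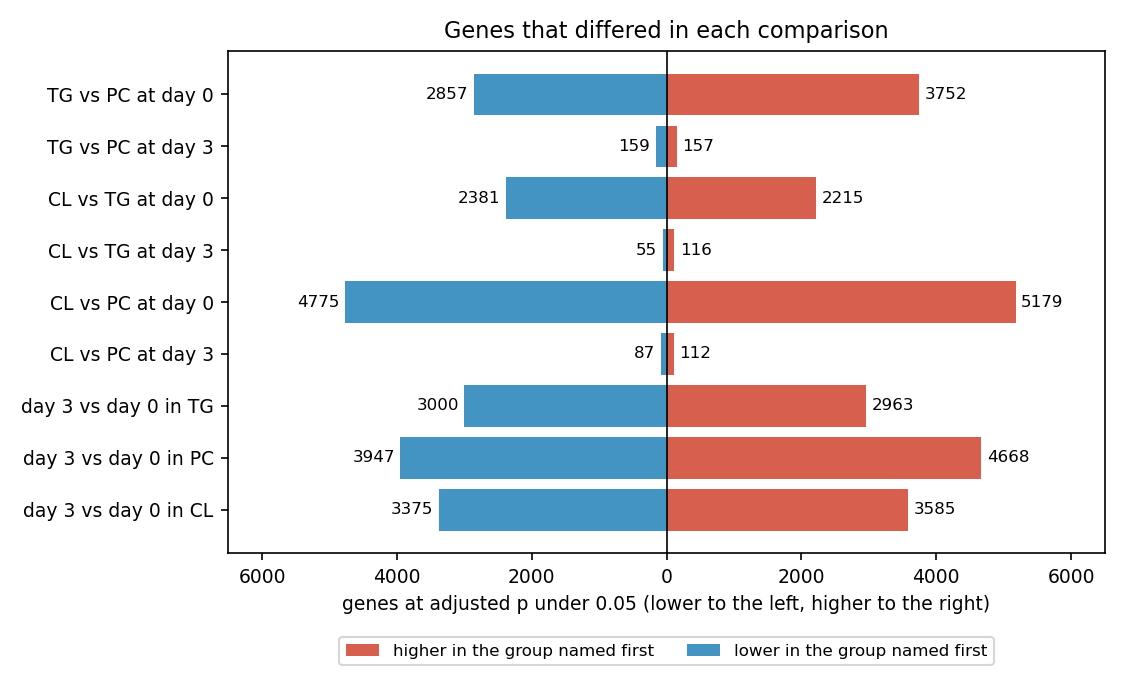
Number of genes at an adjusted p under 0.05 in 9 comparisons (edgeR quasi-likelihood test), with bars to the right for genes higher and to the left for genes lower in the group named first. Directions are relative to the TMM scaling. Between any 2 cultivars more genes differed on day 0 (4596 to 9954) than on day 3 (171 to 316).

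The comparison of day 3 with day 0 asks how cut midrib tissue changed in storage, within each cultivar. No uncut midribs were among the samples, so effects of cutting and of cold storage cannot be told apart. Storage change and storage response here mean only the change from day 0 to day 3. LOC111897754 rose in all 3 cultivars, from 0.1757 ± 0.195 to 80.76 ± 19.7 CPM in TG, from 2 counts to 107.2 ± 8.66 CPM in PC, and from 0.9957 ± 0.0272 to 174.1 ± 9.17 CPM in CL (SD, n = 2). LOC111881939 rose 124-fold in TG to 42.55 ± 21.4 CPM, at least 1535-fold in PC to 108.8 ± 5.17 CPM, and from 2 counts to 68.61 ± 1.41 CPM in CL. LOC111901693 fell in TG from 102.5 ± 30.2 to 0.5497 ± 0.396 CPM, in PC from 59.45 ± 56.8 to 0.3797 ± 0.486 CPM and in CL from 405.5 ± 1.39 to 0.8204 ± 0.444 CPM. LOC111886538 fell from 88 ± 14.9 CPM to 4 counts in TG, 532-fold from 105 ± 40.6 CPM in PC and 124-fold from 39.5 ± 37.9 CPM in CL. The highest adjusted p among these 12 changes was 0.00128, for LOC111901693 in TG (edgeR quasi-likelihood test). Single libraries moved the sizes, most where a group held few counts. The log2 change of LOC111886538 in TG went from -11.01 to -14.96 without TG day 3 replicate 2 and to -9.98 without replicate 1, that of LOC111881939 in CL from 11.21 to 14.63 without CL day 0 replicate 1 and to 10.39 without replicate 2, and that of LOC111897754 in PC from 11.99 to 15.28 without PC day 0 replicate 1 and to 11.10 without replicate 2. That of LOC111901693 in PC went from -7.40 to -5.79 without PC day 0 replicate 1 and to -10.63 without PC day 3 replicate 2, in TG from -7.55 to -8.55 without TG day 3 replicate 2 and to -6.92 without replicate 1, and in CL from -8.89 to -9.64 without CL day 3 replicate 1. LOC111886538 in CL went from -7.00 to -5.36 without CL day 0 replicate 1 and to -7.75 without replicate 2. In TG the log2 change of LOC111881939 went from 6.95 to 6.34 without TG day 3 replicate 1, and that of LOC111897754 from 8.89 to 10.96 without TG day 0 replicate 2, with a smaller move down without replicate 1.

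In TG 5963 genes changed between day 0 and day 3, 2963 up and 3000 down. PC had 8615 changed genes, 4668 up and 3947 down, and CL had 6960, 3585 up and 3375 down. In all 3 cultivars together, 1246 genes rose and 1141 fell, where independent lists would share 105 and 84, out of 12644 genes that changed in at least one cultivar. Across genes, which are not independent replicates, the log2 changes of TG and CL had a Pearson correlation of 0.61, those of TG and PC 0.46 and those of PC and CL 0.42. Opposite changes in a pair of cultivars were found for 690 genes. The counts fell to 2638 in TG without TG day 3 replicate 1 and to 3922 in a fit of only the TG groups, to 5532 in PC without PC day 3 replicate 1, and to 3925 and 3952 in CL without CL day 3 replicate 1 or 2. Without a scaling factor the CL split became 5546 up and 2088 down.

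The high- and low-browning cultivars were compared in their change from day 0 to day 3. The test was of the difference between the TG and PC changes. LOC111893813 rose in TG 56.7-fold from 0.1947 ± 0.168 to 11.03 ± 0.767 CPM while it fell 9.64-fold in PC from 91.59 ± 74.8 to 9.497 ± 0.42 CPM, a difference of 9.12 on the log2 scale (SE 1.05, adjusted p = 0.00169). LOC111918964 fell in PC from 287.3 ± 148 to 1.905 ± 1.33 CPM and stood at 1.227 ± 0.228 and 2.175 ± 1.67 CPM in TG, a log2 difference of 8.09 (SE 0.92, adjusted p = 0.00165). The difference of LOC111893813 was 7.88 without PC day 0 replicate 2 and 10.41 without TG day 0 replicate 2, and that of LOC111918964 was 6.98 without TG day 3 replicate 1 and 9.11 without PC day 3 replicate 2. LOC111908135 rose at least 1891-fold in PC, from 0 counts to 134.1 ± 14.2 CPM, against 4.03-fold in TG from 6.097 ± 4.89 to 24.59 ± 18.2 CPM (adjusted p of the difference 0.00322). The fitted log2 difference of -13.58, which depends on the prior count, was -12.35 without TG day 0 replicate 1 and -14.64 without TG day 3 replicate 2. LOC111888523 rose at least 567-fold in PC, from 0 counts to 40.21 ± 5.49 CPM, and was at 10.26 ± 11.4 and 39.23 ± 5.89 CPM in TG on day 0 and day 3. Its difference had an adjusted p of 0.0419 and passed the threshold under 10 of 20 alternatives, with adjusted p up to 0.157. Without TG day 0 replicate 2 its fitted log2 difference moved from -11.91 to -9.70 (adjusted p = 0.137).

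**Figure D3:**
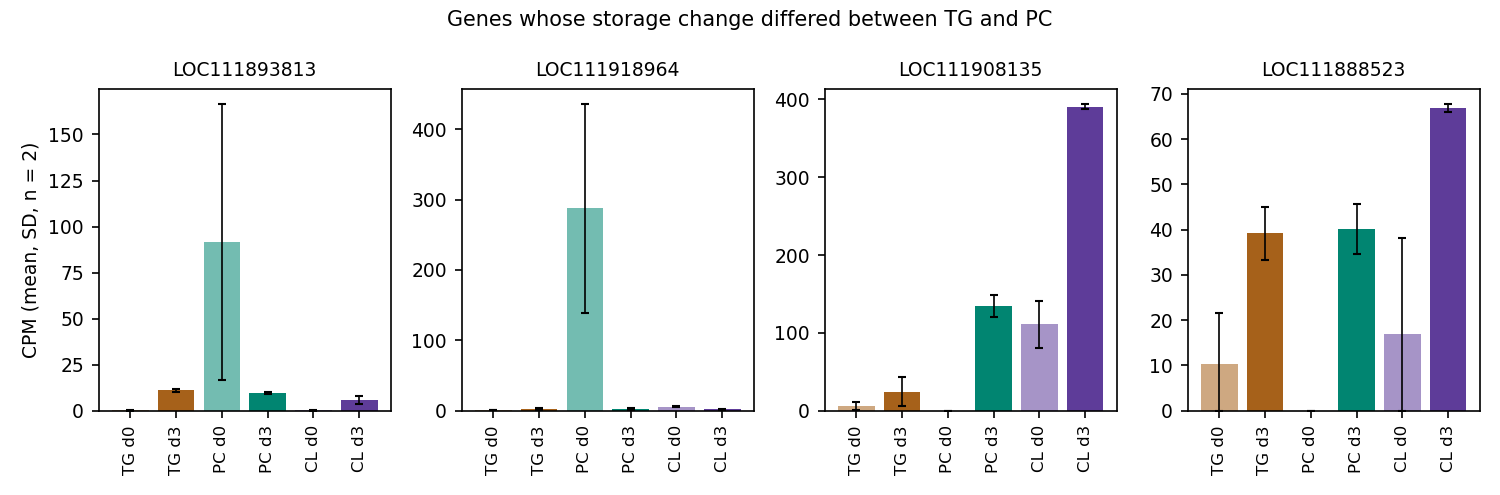
Mean CPM of the 4 genes named for the difference in storage response, with 1 bar per cultivar and day (d0 and d3, 2 libraries each) and error bars of 1 SD that end at 0. LOC111893813 and LOC111918964 were highest in PC on day 0 (91.59 and 287.3 CPM), where LOC111908135 and LOC111888523 had 0 counts.

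This difference passed the threshold for 2652 genes, 1035 with a more positive change in TG and 1617 with a more negative change in TG. Of them 2542 also differed between TG and PC on day 0, a test that shares the day 0 libraries, and 2517 of those had a smaller difference on day 3. The median absolute log2 fold change of the 2652 genes between TG and PC was 1.95 on day 0 and 0.32 on day 3 (1.94 and 0.32 with groups at 0 counts set to the floor). Over all tested genes it was 0.73 and 0.32. The 2652 genes were selected for a change in this difference, and the 2542 also for a day 0 difference, so these values are partly set by the selection. The count was 1007 and 1186 without PC day 3 replicate 1 or 2, 1409 and 1378 without TG day 3 replicate 1 or 2, 1611 without PC day 0 replicate 2 and 1706 without TG day 0 replicate 2. It was 1765 in a fit of only the TG and PC groups, 4414 with DESeq2 and 4492 with all 18 columns, and without a scaling factor the split was 1372 to 1342.

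The comparison of CL with each parent asks where the selected line stands between them, here over day 0 and day 3. Against PC, CL expressed the 2 genes named above as higher in TG. LOC111921163 stood in CL at 42.51 ± 0.443 CPM on day 0 and 37.49 ± 9.24 CPM on day 3, at least 600-fold and at least 596-fold above PC, and GeneID_111886954 at 30.46 ± 10.2 and 26.7 ± 2.77 CPM, at least 430-fold and at least 424-fold above PC. LOC111887882 was lower in CL, at 0.3966 ± 0.0483 CPM against 23.2 ± 3.37 CPM in PC on day 0 and 0.2563 ± 0.124 against 7.489 ± 1.79 CPM on day 3, a log2 fold change over days of -5.33 (SE 0.76, adjusted p = 0.000678). On day 3 alone this difference did not pass the threshold (adjusted p = 0.0903). LOC111893813 was also lower over days (log2 fold change -4.45, SE 0.51, adjusted p = 0.000253), 306-fold on day 0 and 1.63-fold on day 3, where the difference did not pass the threshold (adjusted p = 0.755). Its log2 fold change over days was -3.84 without PC day 0 replicate 2 and -5.15 without CL day 0 replicate 1. In total 7981 genes differed between CL and PC, 4147 higher and 3834 lower in CL, and 4604 of these at least 2-fold. Without a scaling factor the split was 2526 higher and 7057 lower.

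Against TG, CL expressed the 2 genes named as higher in PC. LOC111900676 stood in CL at 84.22 ± 8.58 CPM on day 0 and 38.82 ± 2.31 CPM on day 3, against 4 counts of TG on day 0, all in replicate 1, and at least 647-fold above TG on day 3. Its fitted log2 fold change over days moved from 12.36 to 14.33 without TG day 0 replicate 1. GeneID_111888072 stood in CL at 67.68 ± 19.3 and 60.73 ± 3.92 CPM, with a ratio to the 2 counts of TG on day 0 of 3348. Its 95% counting interval of 926 to 27649 takes each count as independent and is too narrow if both mates were counted. TG had 2 counts on day 3 as well, and on both days they lay in replicate 1. The fitted log2 fold change over days moved from 11.45 to 12.98 without TG day 0 replicate 1 and to 12.96 without TG day 3 replicate 1. LOC111898383 was lower in CL than in TG, at 0.5425 ± 0.289 against 9.085 ± 0.952 CPM on day 0 and 2.938 ± 0.413 against 35.85 ± 1.63 CPM on day 3 (log2 fold change -3.84, SE 0.26, adjusted p = 5.4e-05). LOC111891021 was lower by a log2 fold change of -4.74 (SE 0.90, adjusted p = 0.00761), with TG at 302.2 ± 370 CPM on day 0. On day 3 alone the difference did not pass the threshold (log2 fold change -4.95, adjusted p = 0.162). Without TG day 0 replicate 1, which held 29634 counts against 1806 in replicate 2, this fold change was -3.29 (adjusted p = 0.0175), without CL day 0 replicate 2 it was -5.46, and without CL day 3 replicate 1 the adjusted p was 0.0536.

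Over days 3954 genes differed between CL and TG, 1907 higher and 2047 lower in CL, and 2057 of these at least 2-fold. The count was 1627 and 2179 without CL day 3 replicate 1 or 2 and 2185 without TG day 3 replicate 2, and without a scaling factor the split was 1218 higher and 3835 lower. On single days CL differed from TG in 4596 genes on day 0 and 171 on day 3, and from PC in 9954 genes on day 0 and 199 on day 3. Without any one of their 4 libraries the day 3 counts were 60 to 71 against TG and 60 to 75 against PC, and the day 0 counts were 2594 (without CL day 0 replicate 2) to 3195 and 6777 to 9223. In fits of only the groups compared, CL differed from TG in 2182 genes on day 0 and 761 on day 3, and from PC in 7321 and 2128, while DESeq2 called 713 and 657 genes on day 3.

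At the 265 genes that differed between TG and PC in the same direction on both days, CL stood for most near the level of one parent. With PC at 0 and TG at 1 on the log2 CPM scale, averaged over days, the position of CL was above 0.75 for 134 genes, called TG-like here, below 0.25 for 81 genes, called PC-like, and between for 50. Of the genes higher in TG, 87 were TG-like and 25 PC-like in CL. Of the genes higher in PC, 47 were TG-like and 56 PC-like.

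**Figure D4:**
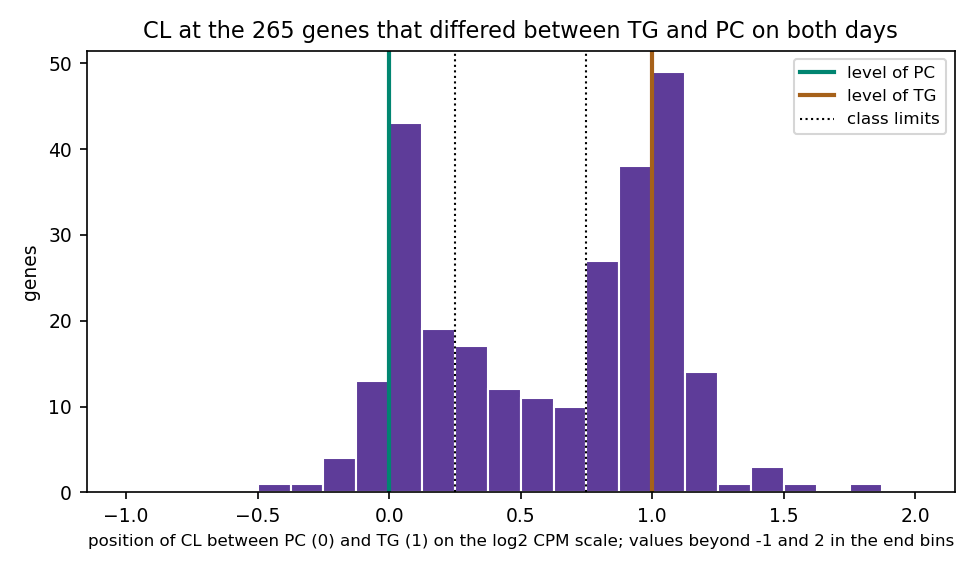
Number of genes by the position of CL between PC (0, green line) and TG (1, brown line) on the log2 CPM scale, for the 265 genes that differed between TG and PC on both days. Dotted lines at 0.25 and 0.75 limit the classes, which hold 81 PC-like, 50 intermediate and 134 TG-like genes.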

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

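The tests of the day 2 columns in this part were chosen after the result was seen, and the differences in storage response that involve CL and the single-day comparisons of CL with TG were not in the design and were added after the files had been seen. The tests of the day 0 excess were set after a first fit had shown the counts of TG against PC, the component scores and the library correlations, but before their own counts were seen. Fitted log2 differences of genes with a group at 0 counts depend on the prior count and are not bounds.

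The change from day 0 to day 3 differed between cultivars in tests of the difference itself, which do not show that storage was the cause. This held for 2652 genes between TG and PC, for 5188 between CL and PC and for 214 between TG and CL. The last count was 1426 with DESeq2, 1081 with all 18 columns taken as counts, 493 with no filter on low counts and 489 without a scaling factor, and it was 1 to 678 without any one library: 1 without TG day 3 replicate 1 or CL day 3 replicate 2, 2 without CL day 3 replicate 1, 84 without TG day 3 replicate 2, 96 without CL day 0 replicate 2, 109 without TG day 0 replicate 2 and 678 without TG day 0 replicate 1. The count between CL and PC was 2330 without CL day 3 replicate 2, 2639 without PC day 3 replicate 1, 2892 without CL day 3 replicate 1, 3235 without PC day 0 replicate 2 and 3398 without PC day 3 replicate 2. Without a scaling factor its split of 2315 more positive and 2873 more negative changes in CL turned to 3916 and 1836, and that between TG and CL went from 91 and 123 to 91 and 398. Among single genes, the log2 difference between the TG and PC changes was 9.12 for LOC111893813, 8.09 for LOC111918964, -13.58 for LOC111908135 and -11.91 for LOC111888523, the latter pair with 0 counts in PC on day 0. Without single libraries, LOC111893813 went to 7.88 (PC day 0 replicate 2) or 10.41 (TG day 0 replicate 2) and LOC111918964 to 6.98 (TG day 3 replicate 1) or 9.11 (PC day 3 replicate 2). In the same way LOC111908135 went to -12.35 (TG day 0 replicate 1) or -14.64 (TG day 3 replicate 2) and LOC111888523 to -9.70 (TG day 0 replicate 2).

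More genes differed between TG and PC on day 0 (6609) than on day 3 (316). Without PC day 0 replicate 2, the library whose loss lowered the count most, 3813 genes still differed on day 0, which argues against a single divergent library. With all libraries thinned to the smallest total the counts were 6600 and 322, and without the 100 most abundant genes 6534 and 328, which argues against depth and against a few abundant genes. A spread shared between days was not the whole source either. Replicates differed more in the day 0 groups (chi-square over degrees of freedom 56.7 to 84.9) than in the day 3 groups (11.2 to 36.8). Fits of only the groups compared gave 2873 on day 0 and 889 on day 3, a smaller excess. The PC day 0 heads were not needed for such an excess, since CL and TG differed in 4596 genes on day 0 and 171 on day 3. In fits of only those groups the counts were 2182 and 761. Handling or harvest that differed among all 3 cultivars before day 0 was not tested and is confounded with cultivar, so a convergence of the cultivars during storage may be biological only as a hypothesis.

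In data that the comparisons did not use, at least 98.9% of the rows of a day 2 column with 200 or more day 0 and day 3 counts lay within 1 count of the value computed from those days, and the other 435 such rows within 1 count of the plain mean. For the rows with 200 or more counts, the deviation was also taken from the mean of both days scaled to the same sum, without a constant. Its mean square was at most 0.0112 of the counting variance, where separately sequenced tissue would give 1 or more. Of all values of 100 or more in a day 2 column, at most 50.5% were even, against 68.4% to 74.6% on the other days, which argues against pooled and subsampled reads. The median absolute log2 deviation was 0.00079 to 0.00192 from the columns of the same replicate number and 0.156 to 0.219 from those of the other. The remaining candidate explanation is arithmetic on the day 0 and day 3 columns. It leaves open up to 391 rows of a column with 1 or 2 counts where both days had 0. Beyond separately sequenced tissue, no biological explanation was tested.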

How the results depend on the processing

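Of 148 alternative counts for the 8 comparisons, 120 were within 1.5 times the reported count and 28 were further away. Whether more genes were higher or lower turned or became equal in 40 of the 148. Among these, the counts without a scaling factor were 2902 higher and 3968 lower for TG against PC on day 0, 2526 and 7057 for CL against PC, 3418 and 2502 for storage in TG, and 1372 and 1342 for the difference in storage response. Of 560 values for the named genes, 549 kept direction and call, 11 lost the call and 0 turned. The named genes were chosen from these same data for large changes past the threshold, so this was largely set by the selection. It does not describe the called genes in general. Of the 6609 genes called for TG against PC on day 0, 2794 were also called in a fit of only those groups. The alternatives added after seeing the data are named in the methods. In a fit of only the groups compared, TG against PC gave 2873 on day 0 and 889 on day 3. Storage in TG gave 3922 and the difference in storage response 1765. The main fit shares a spread between days, although replicates differed more in the day 0 groups than in the day 3 groups. Such a spread lies too low for day 0 and too high for day 3, the direction of the shifts of TG against PC. How much of the shifts it gave was not tested. DESeq2 called 833 genes for TG against PC on day 3 and 4414 for the difference in response. All 18 columns taken as counts gave 608 and 4492, where the added columns are computed from the others. A 2-fold minimum left 4604 genes for CL against PC and 2057 for CL against TG. Not among the 148 was a simpler model of the 8 libraries with a day term, used for the splits below. It called 455 and 1153 genes, against 7981 and 3954 in the main fit. Leaving out each library in turn gave 3813 to 6354 for TG against PC on day 0, 126 to 179 on day 3, 2638 to 4846 for storage in TG, 5532 to 7857 in PC and 3925 to 5057 in CL, 5506 to 8117 for CL against PC, 1627 to 3445 for CL against TG and 1007 to 3886 for the difference in response. In these fits the lone library of a group is assumed to vary like the other groups. With the replicate number as a block the counts were 6190 and 245 for TG against PC on day 0 and day 3, 5583, 8318 and 6593 for storage in TG, PC and CL, 7637 and 3608 for CL against PC and TG, and 2395 for the difference in response. Deviations of same-numbered libraries correlated at -0.09 to 0.07 over 15 pairs of groups, 0 of them over 0.1, so they gave no sign of pairing. The replicate 1 library had the larger total in every tested group, which the CPM scaling removes. A batch shared by same-numbered libraries is therefore not excluded. The comparisons planned for day 2 and the gene list tests, with their alternatives, were not run. At 2 libraries per group the simulated recovery of 2-fold changes was 12% for TG against PC on day 0 and 0% for the difference in response. The adjusted threshold was stricter in the simulation, so these shares do not give the recovery in the data. Thinning every library to the smallest total left all 8 counts within 1.5 times.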

Other observations

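The limits for genes on or off, the classes of CL and the spacing of neighbouring genes by 50 were chosen after the data had been seen. A gene was counted as on with at least 1 CPM in all 4 libraries of a cultivar and off with at most 3 counts in each of them. Off refers to assigned reads only, and why a gene had few or no counts was not tested. By this measure 38 genes were on in TG and off in PC, of which CL had 19 on, 10 off and 9 in neither state. Another 40 were on in PC and off in TG, of which CL had 12 on, 20 off and 8 in neither state. The same limits set between the replicate numbers of a single cultivar gave 0 genes.

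CL also had 8 genes on that were off in both of its parents, all with 0 counts in the 8 TG and PC libraries. Among them LOC111890099 stood at 19.2 ± 0.096 CPM on day 0 and 10.2 ± 0.169 CPM on day 3, and GeneID_111902100 at 9.92 ± 1.39 and 10.9 ± 0.944 CPM (SD, n = 2). In the opposite state were 2 genes that had 0 counts in the 4 CL libraries. LOC111904360 stood at 2.09 ± 0.27 CPM in TG and 5.67 ± 0.181 CPM in PC on day 0, and GeneID_111906364 at 3.34 ± 0.868 and 13.7 ± 0.00285 CPM. These 4 genes were chosen after their values were seen. Inheritance of each gene's state unchanged from either TG or PC does not give such genes. Other explanations were not tested. These genes therefore do not decide how far the TG and PC plants sampled stand for the parents of CL.

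Genes that differed between TG and PC on both days lay near each other. Of the 265, 231 were placed on the Lsat_Salinas_v11 chromosomes, and 33.3% of those lay within 5 tested genes of another, against 10.5% for random genes (permutation p = 0.0001, the smallest that 10000 draws can give).

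It was then asked whether CL resembles the same parent in runs of neighbouring genes, as inherited chromosome segments would give. Of the placed genes, the 183 that were TG-like or PC-like were kept and those between were left out before pairs were formed. In 76.4% of 174 consecutive pairs both genes were of the same class, against 51.6% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Tandem copies that share reads might give such runs, but with genes at least 10 tested genes apart the share was still 70.6% of 126 pairs against 50.9% in shuffles (permutation p = 0.0001, the smallest they can give). At 50 tested genes apart it was 63.7% of 91 pairs against 52% (permutation p = 0.011). The shuffles did not keep the direction of the difference between TG and PC. Of the genes higher in TG, 87 were TG-like and 25 PC-like, and of those higher in PC, 47 and 56. Neighbours that share a direction could therefore raise the share, which was not tested. Inherited segments remain a candidate explanation, with the further limit that the gene order is that of the reference assembly. The genes on or off in CL alone were not explained either, and they do not decide its parentage.

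For CL against PC and CL against TG over days, the 8 libraries were also split in other ways, in a simpler model with a day term. Day separated the libraries, so they can be exchanged only within a day, which leaves 18 splits, too few for a share under 0.05. The real split called 455 genes for CL against PC, where the main fit called 7981, and the highest other split 0. For CL against TG the real split called 1153, where the main fit called 3954, and the highest other split 0. So 1 of 18 splits, the real split, was as large in each case. The simpler model leaves differences in storage response in the spread. The test set beforehand counted splits across days as well, of which 34 could be fitted, and its limit of 5% did not allow for the difference between days. The other splits leave the cultivar difference in the spread, so few calls were to be had from them.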
